A study of Mus musculus with 6 samples.

How the data were processed

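RNA was measured in 6 libraries of mouse spleen naive CD4+ T cells that had been activated on plate-bound antibodies against CD3 (2 µg/ml) and CD28 (1 µg/ml) and cultured for 24 h with a recombinant form of the mouse protein CIRP (cold-inducible RNA-binding protein; rmCIRP, 1 µg/ml) or with the same volume of phosphate-buffered saline (PBS). Per the labels' protocols, poly(A) RNA was selected from total RNA with oligo(dT) beads, fragmented and copied with dUTP in the second strand, which keeps the strand of origin, and the libraries were read from both ends on an Illumina NovaSeq instrument. Poly(A) selection leaves out RNAs without a tail, and the amplification step carried no molecular identifiers, so fragments are not independent molecules. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9 and inspected with FastQC, and the genome build was GRCm38. The aligner, the counting program, its use of strand and the annotation release are not given in the sources used here.

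The deposited table held 55401 genes with coordinates, annotation terms and, per the file headers, an FPKM value (fragments per kilobase of transcript, scaled to the depth of the library) and a count for each library. The authors' FPKM values are scaled for depth and gene length and set to 0.0001 where the count is 0. The deposited counts are whole numbers that are not scaled for depth, and their low values show that they are estimated counts, not plain read counts. Between 1007 and 1334 genes per library stood at a value of 4, against 361 to 446 at 3 and 202 to 246 at 5, with further excesses at 8 and 12. A single fragment was therefore worth about 4 of these units. Because the estimated counts were whole as deposited, rounding changed nothing. Of the gene identifiers, 55141 were found in GENCODE M21, which is on GRCm38, and 94.23% of those had the same coordinates there. The coordinates given are those of the deposited table.

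Estimated counts summed to 63952865, 58019845 and 42274851 in PBS replicates 1, 2 and 3 and to 67512982, 62235453 and 64045022 in rmCIRP replicates 1, 2 and 3. At 4 units per fragment these totals stand for about 10568712 to 16878245 fragments. The 10 most abundant genes took 4.79% to 5.22% of a library. No 2 libraries held identical counts. With counts divided by 4, the chi-square per degree of freedom over genes between libraries of the same group ran from 12.52 to 48.46, so no pair agreed within sampling noise and none was merged.

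Samples were grouped by their titles. For 6 of 6 samples the treatment field of the labels names the opposite treatment from the title. The column names of the deposited table name the condition too and go with the titles. All directions given rest on the titles and would turn around if the treatment field were right. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

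The test planned before the data were examined was limma on log2 FPKM, to be replaced by edgeR if the table also held counts. It did, so the comparison used edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood test on the estimated counts, TMM scaling and a two-sided Benjamini-Hochberg adjusted p under 0.05. The 11655 genes with a mean FPKM of at least 1 over the 6 libraries were tested, and they held at least 99.17% of the counts of each library. TMM factors lay between 0.984 and 1.016. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, and 95% intervals from its degrees of freedom. CPM values are the estimated counts scaled to library size with the TMM factors.

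Gene lists were fixed before the data were examined: 26 lists for pathways and T cell programs and 11 lists of cell type markers. The 27 lists with at least 5 tested members were compared with the remaining genes by camera in limma 3.58.1 on log2(FPKM + 1), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27. Camera with an estimated correlation and fry were run beside it. Member counts rest on the edgeR test, over all genes tested and adjusted over the list alone. Terms of the deposited GO and KEGG annotation with 10 to 500 background genes were tested by one-sided hypergeometric tests among the genes past the threshold.

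The genes named were set by a rule fixed in advance; some anchor genes are not reported here. It takes the 8 largest increases and 8 largest decreases past the threshold with a mean FPKM of at least 5, groups that do not overlap and a standard symbol, up to 4 members of smallest adjusted p for each list described, and 21 anchor genes of CIRP biology and T cell activation and differentiation. Tgfb1 was the only gene of the first part. Zfp180 and Rps23-ps1 passed the threshold outside the rule, and they and any further gene outside it were chosen after their values were seen. A symbol with several entries was taken from the entry of highest mean FPKM.

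Counts were simulated from the means and library sizes of this comparison over 11655 genes. The changed genes were drawn from those with a mean above 2 CPM. Of these, the edgeR step recovered 13.4% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 100% of 66 changed 4-fold. It made 8 false calls among 11455 unchanged genes. In the simulated list test, a list moved by 0.3 on the log2 scale was called, and so was 1 of the other 26 lists. Some of those lists share members with the moved list. The simulated genes varied independently of each other, so this run cannot judge the preset inter-gene correlation.

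Alternatives fixed in advance covered the expression minimum, pseudocount, scaling, variance trend, robust fitting, sample weights, a block on replicate number, leaving out each library, 1 entry per symbol, a 2-fold minimum, DESeq2 1.42.0, other list tests and other term sizes. Those on FPKM values used limma. Added after seeing the data were limma on log2(FPKM + 1), counts divided by 4, another edgeR scaling, the older quasi-likelihood method, protein-coding genes alone, removal of a trend with GC content, a term for or removal of 2 libraries, other inputs to camera, the Treg list without Tgfb1, and camera over all terms. Sharing of sequence was measured as the percentage of distinct 50-base words of a gene's GENCODE M21 transcripts that also occur, on either strand, in transcripts of another gene. Figures and these checks used Python 3.11.15.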

Results

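The data were poly(A) RNA-seq profiles of mouse naive CD4+ T cells from spleen, activated through the T cell receptor and CD28 for 24 h with 3 PBS libraries and 3 libraries given rmCIRP at 1 µg/ml. CIRP is an RNA-binding protein that cells make more of in the cold and that acts as an inflammatory signal when released. Estimated counts per library ranged from 42274851 to 67512982, which stand for about 10568712 to 16878245 fragments. The comparison asks how extracellular CIRP alters the transcriptome of T cells during activation. Groups followed the sample titles. The treatment field of the labels names the opposite treatment for 6 of 6 samples, so every "higher with rmCIRP" would read as higher with PBS if that field were right.

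After 24 h with rmCIRP, 3 genes rose and 0 fell among 11655 tested. Tgfb1, which encodes the regulatory cytokine TGF-β1, rose from 4.80 ± 0.494 to 13.6 ± 1.11 FPKM (SD, n = 3 per group). Zfp180, a zinc finger protein gene, rose from 1.25 ± 0.116 to 6.54 ± 0.284 FPKM (SD, n = 3 per group), and Rps23-ps1, a processed pseudogene of the ribosomal protein gene Rps23, rose from 14.6 ± 0.32 to 56.0 ± 1.25 FPKM (SD, n = 3 per group). For each of these genes the 3 rmCIRP libraries lay above the 3 PBS libraries. Zfp180 and Rps23-ps1 were named after their values were seen.

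Tgfb1 (ENSMUSG00000002603, GRCm38 chromosome 7, 25687002 to 25705077, plus strand, protein-coding) had 34.9, 43.8 and 37.7 CPM in PBS replicates 1 to 3 and 101.2, 114.8 and 115 CPM in rmCIRP replicates 1 to 3. Its log2 fold change was 1.51 with a standard error of 0.12, a 95% interval of 1.23 to 1.78 and an adjusted p of 0.0107 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Zfp180 (ENSMUSG00000057101, chromosome 7, 24081924 to 24107713, plus strand, protein-coding) lay 1.61 Mb from Tgfb1. It had a log2 fold change of 2.40 with a standard error of 0.13 and an adjusted p of 0.00234 by edgeR. Rps23-ps1 (ENSMUSG00000100755, chromosome 3, 37714740 to 37715164, plus strand) had a log2 fold change of 1.95 with a standard error of 0.12 and an adjusted p of 0.00324 by edgeR. Its value is uncertain, because 100% of its 50-base words also occur in other genes, among them Rps23. It also lies within Gm5148, a gene on the opposite strand, with strand use in counting not stated. Counts of Gm5148 were 4, 2427 and 1859 in PBS replicates 1 to 3. They were 22, 4 and 5 in rmCIRP replicates 1 to 3. Rps23-ps1 had 6.829, 7.162 and 7.163 CPM with PBS and 27.97, 26.32 and 27.26 CPM with rmCIRP, in the same order. These values argue against reads from Gm5148 as the source of the increase of Rps23-ps1. Rps23 itself stood at 564 ± 55.7 FPKM with PBS and 575 ± 82 FPKM with rmCIRP (SD, n = 3 per group). Of the words of Tgfb1 and Zfp180, 0.5% and 0% were shared with other genes.

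**Figure D1:**
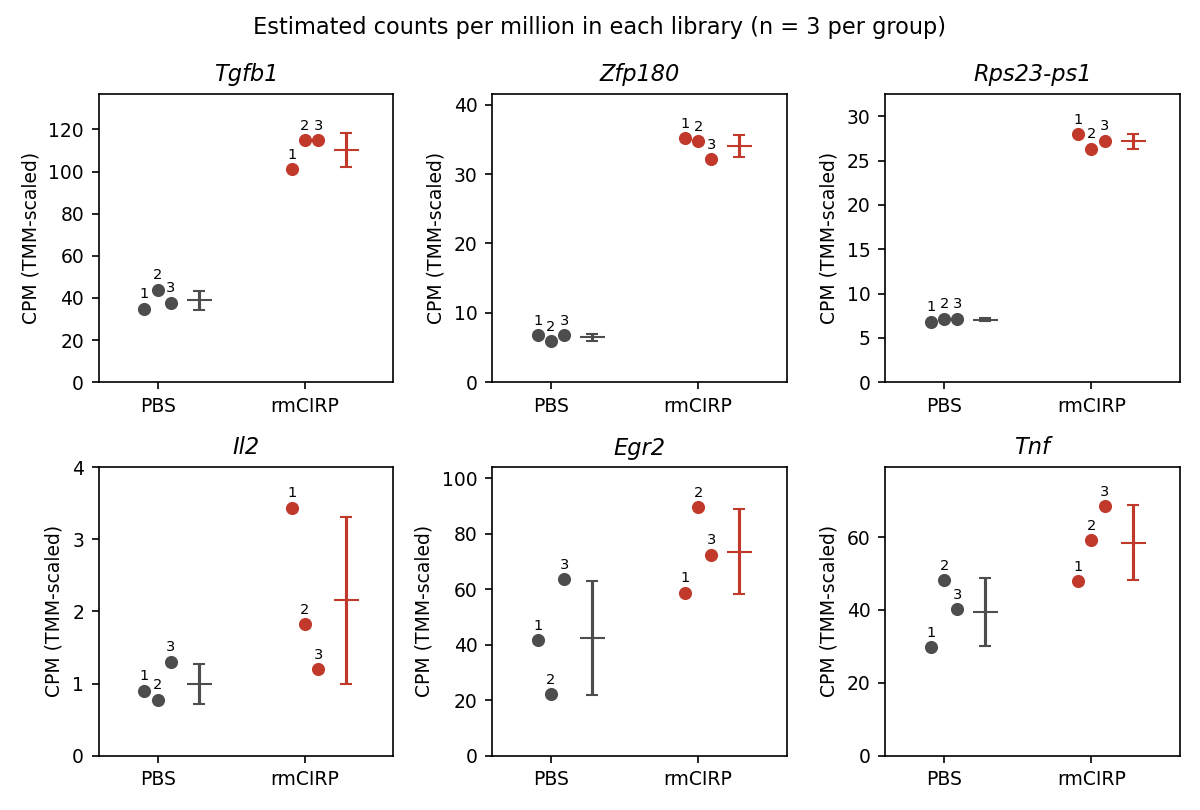
Estimated counts as CPM, scaled by TMM, in each library (points, numbered by replicate) with the group mean and SD (bars), for PBS and rmCIRP, n = 3 per group. Tgfb1, Zfp180 and Rps23-ps1 passed the threshold, while Il2, Egr2 and Tnf had higher means with rmCIRP but an adjusted p of 1 each by edgeR.

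The edgeR test gave 256 genes an unadjusted p under 0.05, of which 124 had higher and 132 lower values with rmCIRP. Chance gives 583 over this number of genes. With a term for rmCIRP replicate 1 and PBS replicate 2 the test gave 571 such genes, and without these libraries 623. The shortfall therefore depended on how these libraries were treated. Of 9 other splits of the libraries into equal groups, 5 gave more such genes than the labelled groups. No gene was lower past the threshold by edgeR or by limma on log2(FPKM + 1), and DESeq2 called 8 genes higher and 9 lower. Groups did not overlap for 690 genes, or 5.9%, where chance gives 10%. The median log2 fold change was -0.004 and the median 95% interval of a gene reached 0.36 to either side on the log2 scale. On simulated counts over 11655 genes, 13.4% of 1.5-fold changes were recovered, all placed in genes with a mean above 2 CPM. The count of genes depended on single libraries: it was 1 without PBS replicate 3, 5 without PBS replicate 1, 6 without PBS replicate 2 and 5 without rmCIRP replicate 2. By edgeR, Tgfb1 had an adjusted p of 0.153 without PBS replicate 3 and 0.0854 without rmCIRP replicate 3, and Rps23-ps1 had 0.0596 without PBS replicate 3. Over all alternatives the adjusted p of Tgfb1 ran from 1.11e-25 to 0.153, that of Zfp180 from 1.64e-64 to 0.0682 (with the replicate block) and that of Rps23-ps1 from 2.1e-50 to 0.0981.

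**Figure D2:**
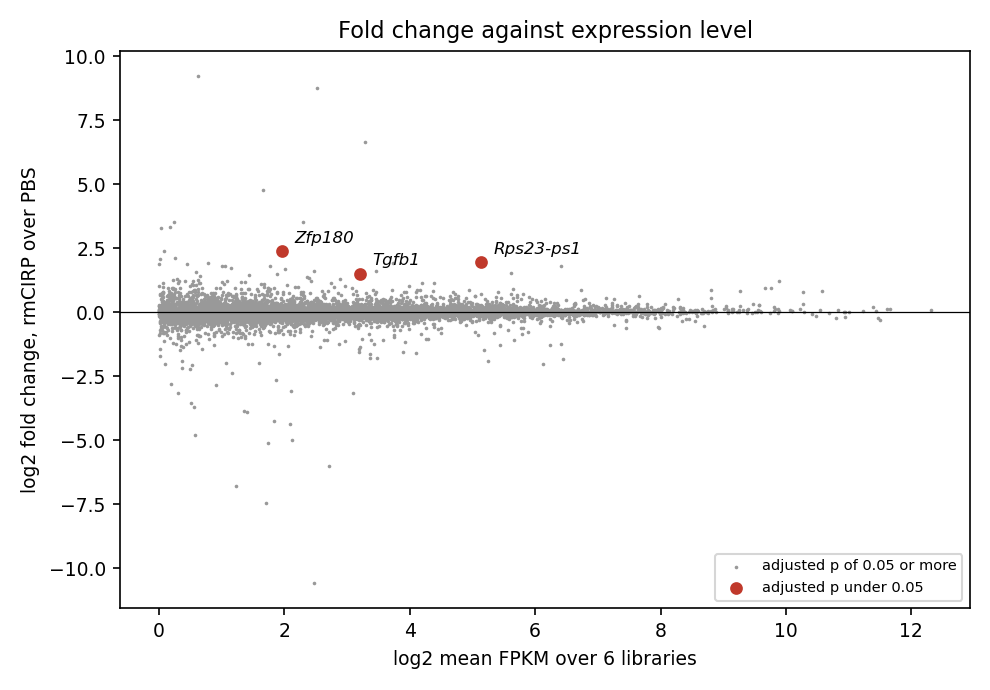
Log2 fold change (rmCIRP over PBS, edgeR) against log2 mean FPKM for the 11655 tested genes; red points are the 3 genes with an adjusted p under 0.05 and grey points all others. The 3 red points lie at log2 fold changes of 1.51, 1.95 and 2.40, and several grey points with larger fold changes did not pass.

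Genes induced early by T cell receptor signalling mostly had higher values with rmCIRP, but whether the list was called depended on the list test. Of 20 tested members, 18 had a positive log2 fold change, with a median of 0.21 and a mean of 0.26, and the list passed camera with an adjusted p of 1.47e-06. The call was lost with an estimated correlation (adjusted p = 0.378). With the preset correlation, 3 of the 9 other splits of the libraries into equal groups called the list too. No single member passed the test, over all genes or adjusted over the list alone (0 of 20 each by edgeR), and 3 had an unadjusted p under 0.05. The list's mean log2(FPKM + 1), relative to the PBS mean, was -0.14, 0.07 and 0.07 in PBS replicates 1 to 3 and 0.19, 0.24 and 0.28 in rmCIRP replicates 1 to 3. Fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.47, and the adjusted p ran from 1.43e-07 to 0.47 over the alternatives.

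Among its members, Tnf, an inflammatory cytokine, had 21.2 ± 4.73 FPKM with PBS and 31.3 ± 5.78 with rmCIRP (SD, n = 3 per group), a log2 fold change of 0.57 with a standard error of 0.20. Tnfrsf4, the costimulatory receptor OX40, had 180.6 ± 15.4 and 209.5 ± 8.67 FPKM (SD, n = 3 per group), a log2 fold change of 0.23 with a standard error of 0.09. Egr2, a transcription factor induced by receptor signalling, had 11.1 ± 5.49 and 19.0 ± 4.15 FPKM (SD, n = 3 per group), a log2 fold change of 0.80 with a standard error of 0.35. Il2, the T cell growth factor, had 11.6 ± 3.27 and 25.0 ± 13.2 FPKM (SD, n = 3 per group), a log2 fold change of 1.15 with a standard error of 0.45. The adjusted p of these 4 genes was 1 by edgeR. Il2 rested on few counts, 58, 44 and 55 in PBS replicates 1 to 3 and 227, 113 and 76 in rmCIRP replicates 1 to 3. Its deposited count and FPKM imply a length of 85 bases against 1144 for its longest transcript, a mismatch that large being found for 1 of 11648 genes. For Tgfb1 the implied length was 8051 bases against 2573, a ratio 2.32 times the median ratio over genes. A ratio within 2-fold of that median was found for 97.0% of genes. The activation markers Cd69 (log2 fold change 0.15, standard error 0.22) and Il2ra (0.09, standard error 0.09) did not differ by more than the spread between replicates.

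**Figure D3:**
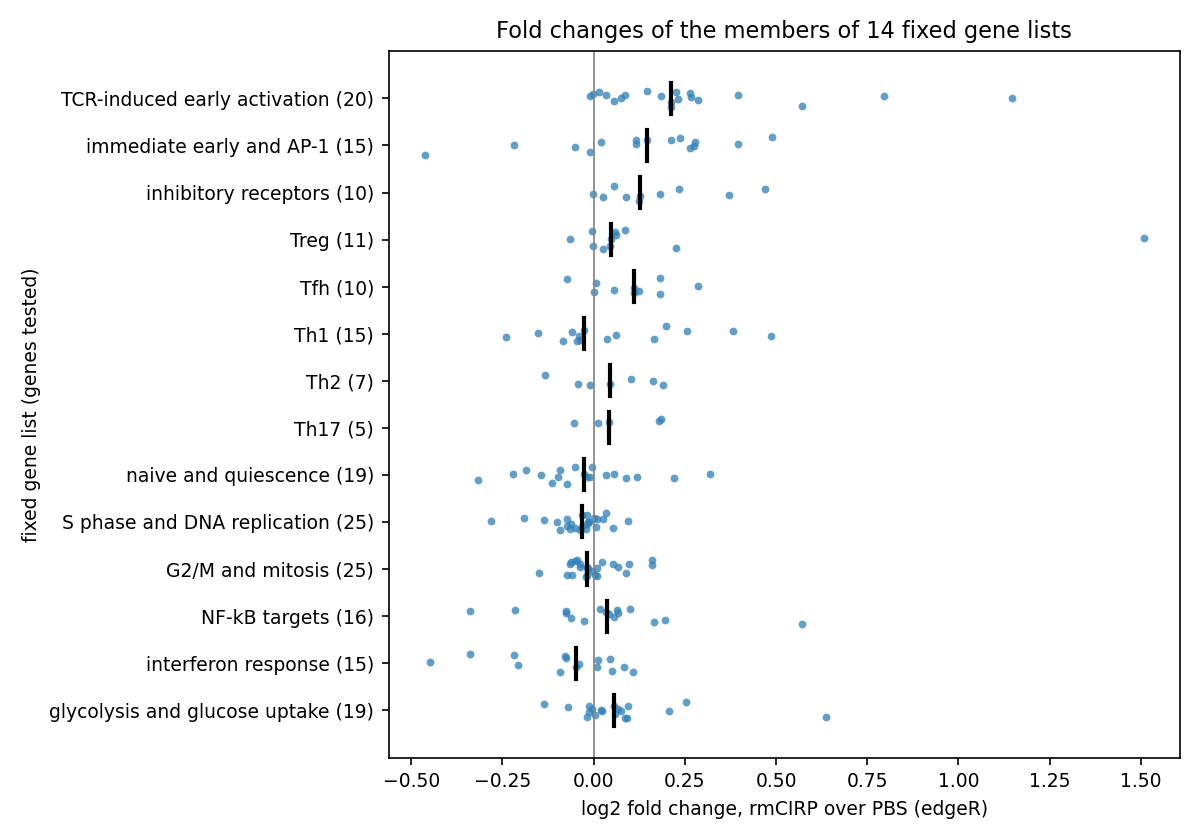
Log2 fold change (rmCIRP over PBS, edgeR) of each tested member (points) of 14 fixed gene lists, with the list median as a black bar and the number of tested members in brackets. The median of the early activation list lies at 0.21, and Tgfb1 at 1.51 stands apart in the Treg list.

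Inhibitory receptors and genes of regulatory T cells (Treg) were the other lists past the camera threshold, both at an adjusted p of 0.0322. Neither passed with an estimated correlation (adjusted p = 0.453 for both). The 3 lists share members, such as Ctla4. Of 10 tested members of the inhibitory receptor list, 9 had a positive log2 fold change, with a median of 0.13. Some members, such as the ligand gene Pdcd1lg2, do not encode receptors. By edgeR 0 members passed singly, over all genes or adjusted over the list alone. Vsir, which encodes the checkpoint molecule VISTA, had the largest at 0.47 with a standard error of 0.20, followed by Pdcd1lg2 at 0.37 with a standard error of 0.25. The increase of Vsir rested mainly on rmCIRP replicate 1. It had 73.7, 66.5 and 90.0 CPM in PBS replicates 1 to 3 and 139.3, 89.0 and 90.4 in rmCIRP replicates 1 to 3. Of 11 tested Treg genes, Tgfb1 rose, 0 fell and 10 did not pass, with the same count of 1 adjusted over the list alone. The median of the list was 0.05, and without Tgfb1 its adjusted p was 0.45. Over the alternatives the adjusted p ran from 6.56e-06 to 0.606 for the Treg list and from 0.0176 to 0.763 for the inhibitory receptors.

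Leaving out PBS replicate 1 (adjusted p = 0.344), PBS replicate 2 (0.0574), rmCIRP replicate 1 (0.119) or rmCIRP replicate 3 (0.162) ended the call of the inhibitory receptors. Leaving out PBS replicate 1 (0.127), PBS replicate 2 (0.19), rmCIRP replicate 2 (0.344) or rmCIRP replicate 3 (0.162) ended that of the Treg list. Foxp3, the Treg master regulator, lay under the expression minimum at 0.923 FPKM with PBS and 0.961 with rmCIRP.

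Lists for helper T cell programs did not pass with all 6 libraries and equal weights. In the Th1 list 7 of 15 tested members had a positive log2 fold change, the median was -0.03 while the mean was 0.06, and the adjusted p was 0.464. Ccl3, a chemokine gene, had a log2 fold change of 0.49 with a standard error of 0.18, and Ifng, the signature Th1 cytokine, had 0.26 (standard error 0.24). The Th2 list had 4 of 7 members positive with an adjusted p of 0.597, and Gata3 stood at -0.13 with a standard error of 0.13. The Th17 list had 4 of 5 members positive with an adjusted p of 0.485, and the follicular helper list had 9 of 10 members positive, a median of 0.11 and an adjusted p of 0.151, with Bcl6 at 0.11 (standard error 0.22); this last list was called higher with sample quality weights and without rmCIRP replicate 1 and PBS replicate 2. Tbx21, the Th1 master regulator, lay under the expression minimum, with counts of 45, 30 and 21 in PBS replicates 1 to 3 and 37, 187 and 262 in rmCIRP replicates 1 to 3. Counts of Il10 were 8, 19 and 8 with PBS and 0, 0 and 4 with rmCIRP, and those of Il4 were 0, 11 and 0 and 29, 0 and 3. Il17a had a count of 0 in 6 of 6 libraries.

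Proliferation and metabolism lists did not pass either in the planned test, although some passed under the alternatives named here. The S phase and DNA replication list had 19 of 25 members with a negative log2 fold change, a median of -0.03 and an adjusted p of 0.148, with Cdc6 at -0.19 (standard error 0.09). The G2/M list had 15 of 25 negative, a mean of 0 and an adjusted p of 0.882, and Mki67, a proliferation marker, stood at -0.01 with a standard error of 0.15. Glycolysis had 13 of 19 positive and an adjusted p of 0.169. Its leading member Gapdh had a log2 fold change of 0.64 with a standard error of 0.15 and an adjusted p of 1 by edgeR, and 25.1% of its 50-base words are shared with other genes. Oxidative phosphorylation had 18 of 25 positive (adjusted p 0.255), ribosome biogenesis 20 of 24 (0.551), cytosolic ribosomal proteins 15 of 25 (0.485) and cholesterol synthesis 12 of 19 (0.772). The mitochondrially encoded mRNAs had 7 of 13 positive, with a median of 0.03, a mean of -0.05 and an adjusted p of 0.882. Their score was 0.336 in rmCIRP replicate 1 against -0.265 and -0.308 in replicates 2 and 3, and the list was called lower without rmCIRP replicate 1, without it and PBS replicate 2, and with sample quality weights. Under the same 3 settings glycolysis was called higher. Ribosome biogenesis was called higher under the last 2 of them, and the S phase list was called lower with a term for rmCIRP replicate 1 and PBS replicate 2.

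For stress and signalling, the immediate early and AP-1 list had 11 of 15 members positive and an adjusted p of 0.148, with Zfp36 at 0.40 (standard error 0.20) and Dusp1 at -0.46 (standard error 0.20). The list was called higher without rmCIRP replicate 1, without it and PBS replicate 2, and with sample quality weights. NF-κB targets had 10 of 16 positive (adjusted p 0.464) and the interferon response list 9 of 15 negative (0.315), with Usp18 at -0.45 (standard error 0.21). The interferon list was called lower with sample quality weights and without rmCIRP replicate 2. The p53 list had 12 of 15 positive (0.464) and was called higher without rmCIRP replicate 1 and PBS replicate 2. The apoptosis list had 11 of 19 negative (0.809) and ER stress 13 of 19 positive (0.485). The heat shock list had 8 of 14 negative (adjusted p 1). The ATF4 list had 8 of 14 positive (0.882), with a median of 0.02 and a mean of -0.01. The naive and quiescence list had 13 of 19 negative (0.882), and migration and chemokine receptors had 10 of 14 negative (0.772). Over the 27 lists, 0 were lower past the camera threshold, 1 was lower at an unadjusted p under 0.05, and both the estimated correlation and fry called 0 in either direction.

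Genes of CIRP itself and of its reported receptors were not called, with 5 of 7 tested members positive and an adjusted p of 0.588. Cirbp had 10.6 ± 1.26 FPKM with PBS and 9.83 ± 0.934 with rmCIRP (SD, n = 3 per group), a log2 fold change of -0.09 with a 95% interval of -0.40 to 0.22. Rbm3, a related cold-induced gene, stood at -0.03 with a standard error of 0.11, and Il6ra at 0.19 with a standard error of 0.14. Of the receptor genes reported for extracellular CIRP, Tlr4 had counts of 16, 0 and 0 with PBS and 12, 8 and 14 with rmCIRP, Trem1 had a count of 0 in 6 of 6 libraries, and Ly96, the partner of Tlr4, had 0.473 and 0.574 FPKM.

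The 14 markers of T cell identity summed to between 1790 and 2180 FPKM per library, above the sum of each other cell type list, and the list had 10 of 14 members positive with an adjusted p of 0.169, and was called higher without rmCIRP replicate 1. The 10 lists of other cell types had fewer than 5 members at the expression minimum and were not tested as lists at that minimum. B cell markers summed to 53.9 to 76.9 FPKM per library, with Ighm contributing a mean of 62.5. CD8 T cell markers summed to 1.6 to 2.14, NK cell markers to 6.05 to 9.82, gamma-delta T cell markers to 2.26 to 3.69, monocyte and macrophage markers to 2.96 to 6.38 and stromal and endothelial markers to 6.23 to 7.93. Dendritic cell markers reached at most 0.712, platelet markers 1.38 and neutrophil markers 4.15. Erythroid genes summed to 58.7 FPKM in rmCIRP replicate 1 against 3.45 to 12.7 in the other libraries. Along the first principal component of log2(FPKM + 1), which held 35.8% of the variance, PBS replicate 2 (25.48) and rmCIRP replicate 1 (22.17) stood apart from the other libraries (-14.92 to -6.79). Along the second, which held 21.1%, these 2 libraries lay at opposite ends (20.88 and -22.39), with the others between -4.72 and 5.88. Without these 2 libraries edgeR called 11 genes and camera 9 lists, and the 3 genes and 3 lists named above were among them.

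Annotation terms showed 0 enrichments among the genes past the threshold in 2701 GO and KEGG terms, by hypergeometric tests in which 151 terms had an unadjusted p under 0.05. Only 2 of the 3 genes carried an annotation, so this test had little to work with. Camera over all terms, chosen after seeing the data, called 0 of 2421 GO terms and 2 of 280 KEGG terms, both higher with rmCIRP. These were the malaria term (16 genes, adjusted p 0.00043), which includes Tgfb1 and the globin genes that were high in rmCIRP replicate 1, and the ribosome term (131 genes, adjusted p 0.0456). With an estimated correlation neither passed (adjusted p = 0.952 for both).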

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

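Alternatives added after seeing the data are limma on log2(FPKM + 1), counts divided by 4, RLE scaling, the legacy quasi-likelihood method, protein-coding genes alone, GC correction, the term for or removal of rmCIRP replicate 1 and PBS replicate 2, other camera inputs, the Treg list without Tgfb1 and camera over all terms. The count of 3 changed genes became 15 with sample quality weights (7 higher, 8 lower), 17 with DESeq2 (8 higher, 9 lower, and 260 genes with no adjusted p) and 11 without rmCIRP replicate 1 and PBS replicate 2 (7 higher, 4 lower), and ran from 1 to 6 when each library was left out; under the other settings without a block it lay between 2 and 4. With the replicate block it was 0 by edgeR, with 208 genes at an unadjusted p under 0.05. Deviations of same-numbered libraries correlated at -0.176, -0.202 and 0.104, and 1 of 6 libraries correlated best with its own number. This cannot exclude a pairing of replicates. The largest correlation, 0.298, was between rmCIRP replicate 1 and PBS replicate 2, which stood apart from the other libraries and have different numbers. Where tested, Tgfb1 was called in 23 of 26 alternatives (log2 fold change 1.33 to 1.66), Zfp180 in 24 of 25 (1.66 to 2.44) and Rps23-ps1 in 23 of 25 (1.86 to 1.97), and none changed sign. Among the other named genes 0 gained a call, and 26 of 2793 gene values changed sign without a call on either side.

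The count of 3 lists became 1 without the expression filter, 1 with quantile normalization, 7 with sample quality weights, 0 with an estimated correlation, 0 with fry, 9 without rmCIRP replicate 1 and PBS replicate 2 and 2 with the replicate block, and it ran from 1 to 6 when each library was left out. The early activation list kept its call in 18 of the 20 alternatives that touch it, all run with the preset inter-gene correlation of 0.01. It lost the call with an estimated correlation and with fry, the 2 alternatives without that setting. By design these 2 tests leave its mean log2 change at 0.237. Fry tests the list against no change, not against other genes. Without each library in turn its mean log2 change ran from 0.17 to 0.27 and the adjusted p from 8.56e-07 to 0.0277. Among all list values 23 lost and 18 gained a call of 540, and 0 reversed. Annotation terms stayed at 0 with other term sizes and with the 2-fold minimum, and were 2 with camera over all terms. For the settings that changed a count, other than those that left out libraries, the cause was not tested.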

Other observations

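The chromosomal-segment test, the naming of genes by their position and the comparison of counts with FPKM were chosen after results were seen. The GC test of the 2 libraries was set after the genes that set them apart had been looked at, but before GC content was measured. The values of the other splits with an estimated correlation, the number of them calling 0 genes and the test of an exchange on genes called from 4 libraries were added after results were seen. The remaining tests were set before their results were seen.

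Of the 40 tested genes of smallest p, 6 were on chromosome 7. Zfp180, Tgfb1, Rinl, Zfp568 and Zfp260 lay between 24081924 and 30107622, and Tpp1 lay far from them, starting at 105744811. The log2 fold changes went both ways, with Zfp260 3.73 times as high with rmCIRP, Zfp568 at a log2 fold change of -1.01 (standard error 0.27) and Rinl at -0.59 (standard error 0.16), each with an adjusted p of 1 by edgeR. Rps23-ps1 on chromosome 3 lay 0.59 Mb from Il2. Gm5148, the gene around Rps23-ps1, had counts of 4, 2427 and 1859 in PBS replicates 1 to 3 and 22, 4 and 5 in rmCIRP replicates 1 to 3.

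The first pattern weighed was the 3 genes past the threshold. Shared sequence argues against reads from copies for Tgfb1 (0.5% of 50-base words shared) and Zfp180 (0.0%), but leaves it open for Rps23-ps1 (100.0%). A chromosomal segment that differs between the animals of the groups stays open. The 40 genes of smallest p held 11 pairs within 5 Mb, against a 95th percentile of 9 in 10000 random draws. With Zfp genes matched that percentile was 10. However, 8 of the pairs were on chromosome 7, whose genes prompted the test. Without it 3 pairs were left against a median of 3, which cannot speak against a segment on chromosome 7 itself. Around Zfp180 and Tgfb1, 161 genes had a median log2 fold change of 0.003, with 82 higher. Of these 161, 9 (5.59%) had an unadjusted p under 0.05 by edgeR, against 2.19% of all tested genes. These values do not decide, since changes in both directions leave a median near 0 and the region was picked around genes past the threshold. Of the 10 splits of the 6 libraries, 3 called at least as many genes as the real split, which called 3, and the highest of the others called 4; with 10 splits no share under 0.05 can be had. A response to rmCIRP stays among the open explanations.

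The second pattern was the early activation list. The tables argue against a trend with GC content or transcript length as its source, since 100.6% of the mean log2 fold change was left once that trend was removed. They also argue against a single library, since the lowest mean without 1 library was 0.168. Members varying together between libraries stay open as a source. Camera with an estimated correlation gave the list an unadjusted p of 0.014, under the bound of 0.05 set beforehand. The 9 other splits gave 0.136 to 0.896. That bound took no account of the 27 lists tested, among which this list had the smallest p, so it cannot decide. Over the 27 lists the adjusted p by that test was 0.378, so the call itself did not hold. With the preset correlation 3 of the other splits called the list. Over all lists, 4 of the 10 splits called at least as many as the real split, which called 3, and the highest of the others called 5; again no share under 0.05 can be had. A response of receptor signalling to rmCIRP stays open as a hypothesis.

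The third pattern was the position of rmCIRP replicate 1 and PBS replicate 2 apart from the other libraries. A trend with GC content is a candidate explanation: across genes, which are not independent replicates, the log2 ratio of these 2 libraries to the other 4 had a Spearman's rho of -0.604 with GC content, and its median fell from 0.20 in the fifth of genes poorest in GC to -0.27 in the richest. An exchange of these 2 libraries between the groups is argued against by the split that exchanges them, which called 0 genes where the labelled split called 3, as the bound set beforehand required; this is weak evidence, since 3 of the 8 remaining splits called 0 genes too. For the 11 genes called from the other 4 libraries, the log2 difference of these 2 libraries was divided by the log2 fold change. This ratio, near -1 under an exchange, had a minimum of -0.187. Tgfb1 (0.726), Zfp180 (1.117), Rps23-ps1 (1.012) and Lrrc61 (1.365) lay near the 1 that the labels predict. These values also argue against an exchange. The remaining genes lay from -0.187 to 0.141, so these 2 libraries did not show their change. Of the 11 genes, 6 kept their direction. The median of 0.123 was under the bound of 0.5 set for that test. The design gives no group that sets these libraries apart, so no biological explanation was tested.

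Globin genes were higher in rmCIRP replicate 1 than in the other libraries. Hba-a2 stood at 19.5 FPKM there, 6.85 times the median of the other libraries, and Hbb-bs at 14.2 FPKM, 6.14 times. Pet117, which lies within Kat14 on the same strand, had 15.7 and 11.3 CPM in rmCIRP replicates 2 and 3 and 0.0151 to 0.0236 CPM in the other libraries.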
